A study of Mus musculus with 514 samples.

How the data were processed

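The series holds 514 samples from single mouse oocytes and embryos, profiled by RNA-seq of polyadenylated RNA with a protocol derived from FLASH-seq. Values for 263 full-length libraries and 110 libraries of reads with a unique molecular identifier (UMI) were used, each matched to a sample by its label, and the other samples were not analysed here. Per the labels, UMI reads mark the 5' ends of transcripts and the other reads cover their full length, and genotyping primers were present during cDNA amplification. The full-length libraries form 22 groups of 4 to 29 at the MII oocyte, early 2-cell (E2C), late 2-cell (L2C), 4-cell (4C) and 8-cell (8C) stages, and the UMI libraries form 14 groups at L2C, 4C and 8C. The prefixes mz, m and z name maternal and zygotic, maternal alone, and zygotic alone; NrKO is a knockout of Nr5a2, EKO of Esrrb and DKO of both. Per the file headers, controls are heterozygous (DHet for both genes, NrHet for Nr5a2) or carry wild-type or floxed alleles (Nrpp).

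The deposited values per library are transcripts per 1000000 (TPM), made by the authors. The programs cutadapt, STAR, RSEM, DESeq2 and genome build mm10 are named in the submitters' notes with no versions. The deposited full-length table had 55168 named genes, against 55247 in the UMI table, and 65 entries with no gene name were left out. Beside these, the authors' deposited tables give a log2 fold change and a false discovery rate (adjusted p-values of their own comparisons) per gene, and per the file headers the authors called genes with over 10 TPM in at least 1 sample of the stage, a 1.5-fold change and a false discovery rate under 0.1. UMI columns summed to 1000000 TPM, and full-length columns to between 814735 and 995883, since some entries of the full-length scale are not used here. TPM keep no read counts, so the sequencing depth is unknown and no counting interval could be given. Between 10655 and 15971 genes exceeded 1 TPM in a full-length library.

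The tests planned before the data were examined assumed read counts, with limma on log2 values as the planned choice for a normalized unit, and the latter was used. Values were transformed to log2(TPM + 1), which understates fold changes of genes near 1 TPM. Genes with at least 5 TPM in at least as many libraries as the smallest group of the stage were tested, a filter that stands in for the planned filter on counts. Each stage was fitted once in limma 3.58.1 (R 4.3.3; limma-trend with empirical Bayes) with group and collection date as factors, so that all groups of a stage shared one spread. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called, with two-sided tests. The labels name no mother or litter, so p-values measure the spread between embryos, some of which may share a mother. Effects at 8C, 4C and L2C were compared in a joint fit with a factor for stage and date. Genes rising or falling in control development were taken at adjusted p under 0.05 and at least 4-fold (2 on the log2 scale). They were chosen in control groups outside the tested comparison, except for mz_NrHet against mz_Nrpp at E2C, where mz_Nrpp also chose the lists. Stage and date could not be separated in these choices. The named chromosome positions come from the GENCODE annotation of mm10, which placed 10671 of the 10876 genes tested at 8C and 12748 of the 13040 tested at E2C.

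The 21 gene lists fixed before the data were examined cover 2-cell genes, oocyte and maternal genes, trophectoderm, inner cell mass and pluripotency, primitive endoderm, polarity with adhesion and Hippo signalling, mitosis, telomeres, DNA repair, DNA replication, p53 targets, ribosome biogenesis, cholesterol synthesis, liver and steroid targets of Nr5a2, oxidative phosphorylation, stress response, and markers of cumulus and granulosa cells, blood, sperm, oviduct epithelium and the Y chromosome. These and the genes rising or falling in development were tested with camera (inter-gene correlation preset to 0.01, and again with an estimated correlation) and fry, given at least 5 tested members, with adjustment over the lists of a comparison. Of 396 list tests, 52 passed with the preset correlation and 2 also with an estimated one. List tests in UMI reads are given with the preset correlation only. Of the 48 oocyte and maternal genes, 35 had full-length values and 47 had UMI values, so part of that list was not tested in full-length reads. With fry 3 lists passed in mz_NrKO at E2C, and at 8C 7 in mz_NrKO, 6 in mz_DKO and 7 between mz_NrKO and mz_EKO. No list passed with fry in the other comparisons. Values on a single date were refitted with a filter of their own, while counts within dates used the genes tested at the stage. The genes named were set by a rule: Nr5a2 and Esrrb; the 8 largest rises and the 8 largest falls among called genes with a group mean of at least 10 TPM, leaving out predicted genes, clones and pseudogenes; and per list up to 4 tested members with the smallest adjusted p. A 10 TPM minimum replaced a planned one on counts. Members of the Zscan4, Tdpoz, Usp17l and Obox families can share reads, and their values are uncertain.

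The alternatives tried were median-of-ratios scaling, no filter, no date factor, a block for the library number, Nrpp as the control, UMI reads, a single date, a lower development fold, and leaving out in turn each library at 4C and each mz_DHet library at L2C. Pseudocounts of 0.1 and 5 TPM, leaving out 3 libraries that stood apart (median rank correlation with their group more than 5 median absolute deviations below that of the stage), control development without a filter, the alternatives for correlations of effects, and checks of the UMI fit at 8C were chosen after seeing the data. Library numbers do not pair groups: the mean correlation of same-numbered libraries lay between -0.0344 and 0.0308 over 19 comparisons. No libraries were identical (0 full-length and 0 UMI), and the highest Pearson correlation between libraries of a group was 0.953. Each count was set against 100 splits of the same libraries. On simulated data with known changes, 98.5% of 4-fold changes were recovered in the E2C design, 81.8% at L2C, 80.3% at 4C and 100% at 8C; for 2-fold changes the shares were 89.6%, 25.4%, 23.9% and 79.1%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

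The UMI libraries were matched to the full-length ones by the rank correlation of gene-centred values. At 4C, 25 of 25 UMI libraries correlated best with the full-length library of the same label, and at L2C 42 of 46 did. At 8C this held for 0 of 39, although 38 matched a library of the same genotype. None of these 39 matched a library dated 23 February 2022, and the library labelled mz_DHet replicate 12 matched full-length mz_NrKO replicate 7. The numbers and dates of UMI libraries at 8C are therefore out of register with the full-length ones, and UMI values at 8C carry that limit. The library labelled mz_DHet replicate 12 stays among their controls. Only some values at 8C, mostly counts of calls, are also given without it.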

Results

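Single mouse oocytes and preimplantation embryos lacking the orphan nuclear receptors Nr5a2, Esrrb or both were profiled by RNA-seq from the MII oocyte to the 8-cell stage. Full-length values were compared for 39 oocytes (9 Nrpp, 18 NrHet, 12 NrKO) and, at the early 2-cell (E2C) stage, for 5 groups of embryos (21 mz_Nrpp, 29 mz_NrHet, 22 mz_NrKO, 12 z_NrKO, 18 m_NrKO). At the late 2-cell (L2C) stage there were 46 embryos (7 mz_DHet, 10 mz_EKO, 10 mz_NrKO, 6 mz_DKO, 7 z_NrHet, 6 z_NrKO). The 4-cell (4C) stage had 25 (6 mz_DHet, 4 mz_EKO, 5 mz_NrKO, 10 mz_DKO) and the 8-cell (8C) stage 51 (21 mz_DHet and 10 each of mz_EKO, mz_NrKO and mz_DKO). The read depth is unknown, since the values are transcripts per 1000000 (TPM). As a stand-in, the median number of genes above 1 TPM per library was 11589 in oocytes, 14000 at E2C, 14313.5 at L2C, 14296 at 4C and 12680 at 8C. TPM are given as mean ± SD over libraries. Log2 fold changes are ± SE with collection date in the fit, and n stands at the first mention of each group in a comparison.

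**Figure D1:**
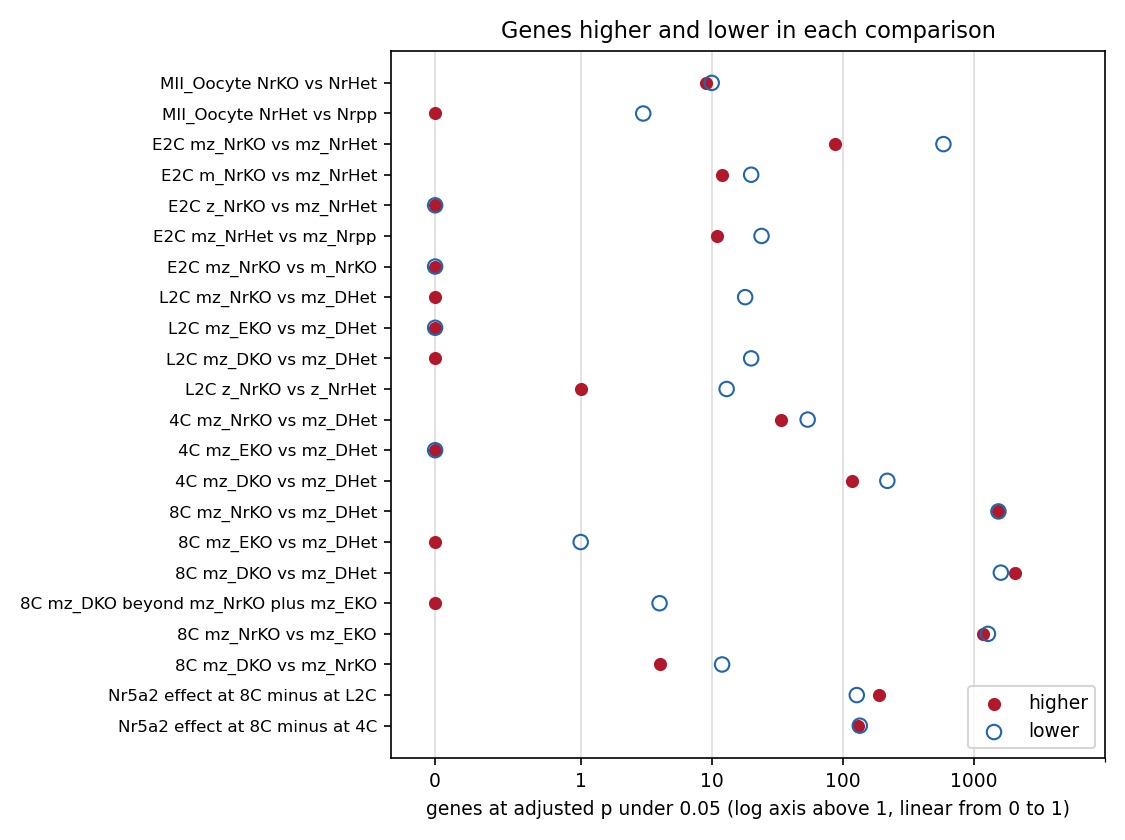
Points give the number of genes higher (up) and lower (down) in the first group of each comparison at an adjusted p under 0.05 in limma, on an axis that is linear from 0 to 1 and logarithmic above. In mz_NrKO 674 genes were called at E2C, 18 at L2C, 88 at 4C and 3075 at 8C, and in mz_EKO 1 at 8C. Group sizes and dates differ between stages, so these counts do not compare the size of the effect. Simulated 2-fold changes were recovered in 89.6% of cases at E2C, 25.4% at L2C, 23.9% at 4C and 79.1% at 8C.

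Transcripts of the targeted genes were still listed in the mutants. The values are given per gene and not per exon, so they cannot show whether the targeted exons were absent. Nr5a2 (ENSMUSG00000026398.14, mm10 chromosome 1, 136842571 to 136960448) stood at 50.5 ± 20.0 TPM in 12 NrKO oocytes and 59.1 ± 21.7 in 18 NrHet oocytes, a log2 difference of -0.04 (adjusted p = 0.919). Its median at E2C was 79.6 TPM in mz_NrKO and 84.4 TPM in mz_NrHet embryos (adjusted p = 0.581). In controls it stood higher later, at 532 ± 113 TPM at L2C, 626 ± 140 at 4C and 472 ± 145 at 8C in mz_DHet. At 8C, Nr5a2 transcripts rose in mz_DKO embryos to 778 ± 174 TPM (log2 fold change 0.64 ± 0.17, adjusted p = 0.0025, higher in 10 of 10). In mz_NrKO they stood at 597 ± 241 TPM (0.38 ± 0.17, adjusted p = 0.0854). A rise was called in UMI reads (0.53, adjusted p = 0.0241), without mz_NrKO replicate 1 (0.49, adjusted p = 0.0228) and with median-of-ratios scaling (0.41, adjusted p = 0.0409). It was not called without the filter, without the date factor, with a block for the library number or on a single date (adjusted p = 0.183, 0.275, 0.448 and 0.431). Esrrb (ENSMUSG00000021255.17, chromosome 12, 86361117 to 86521628) fell at 8C from 47.8 ± 15.5 TPM in mz_DHet to 18.0 ± 8.16 in mz_EKO (log2 fold change -1.56 ± 0.24, adjusted p = 0.000277) and 26.8 ± 10.7 in mz_DKO (-0.96 ± 0.24, adjusted p = 0.00113), lower in all 10 libraries of each. UMI reads gave a steeper fall of Esrrb at 8C, to 1.72 ± 0.618 TPM in 9 mz_EKO libraries against 41.4 ± 14.1 in 16 mz_DHet (-3.88 ± 0.23, adjusted p = 7.72e-16). Before 8C no change of Esrrb passed the test in mz_EKO (log2 fold change -0.71 at L2C and -0.22 at 4C, adjusted p = 0.828 and 0.974). UMI reads gave -1.435 and -0.945 there (adjusted p = 0.811 and 0.86), and the full-length value at 4C was 0.38 without mz_EKO replicate 1.

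**Figure D2:**
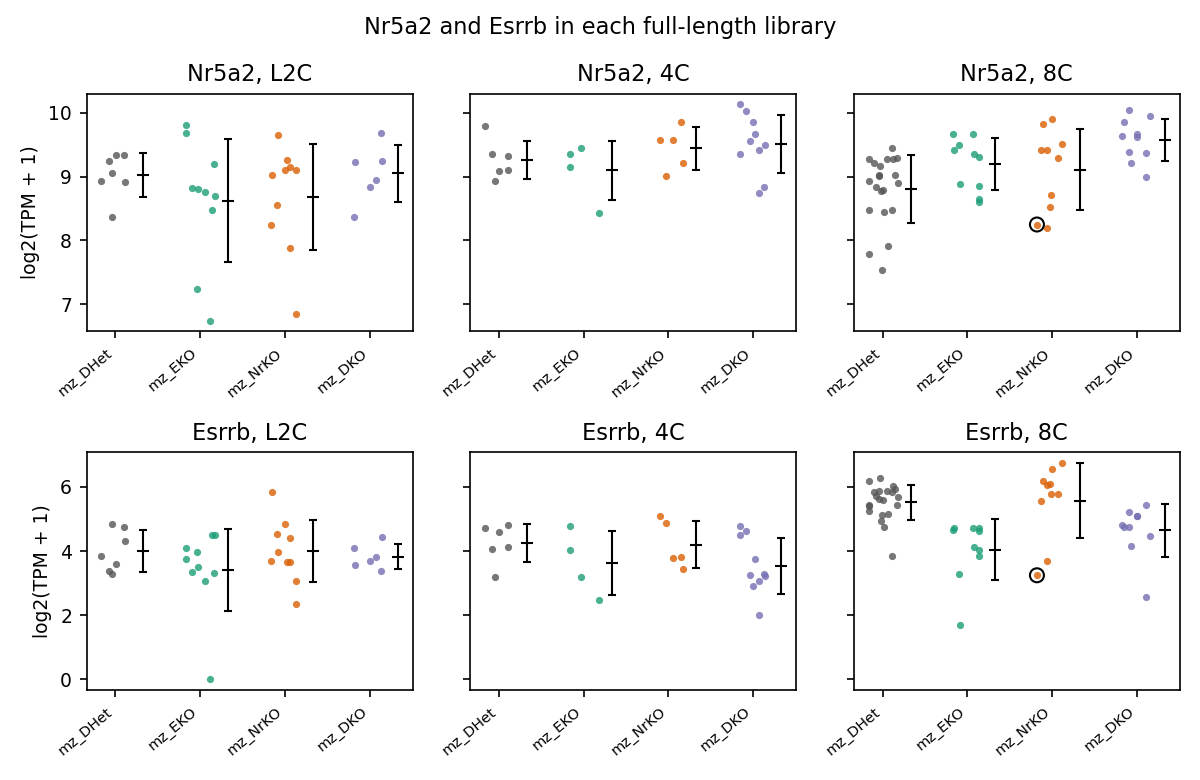
Each point is a full-length library and shows log2(TPM + 1) of Nr5a2 and Esrrb in mz_DHet, mz_EKO, mz_NrKO and mz_DKO embryos at L2C, 4C and 8C, with the mean and SD of each group. Esrrb is lower at 8C in mz_EKO (18.0 ± 8.16 TPM) and mz_DKO (26.8 ± 10.7 TPM) than in mz_DHet (47.8 ± 15.5 TPM), while Nr5a2 transcripts remain listed in every group.

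Control embryos gave the scale of normal development. From Nrpp oocytes to mz_Nrpp E2C embryos, 2204 genes were at least 4-fold higher and 368 at least 4-fold lower among 10927 tested. From mz_Nrpp at E2C to z_NrHet at L2C the counts were 2830 and 3214 of 12707, and from z_NrHet at L2C to mz_DHet at 8C they were 990 and 2081 of 11068. Fewer genes moved between z_NrHet at L2C and mz_DHet at 4C, 50 upward and 174 downward of 10448. These sets served as rising and falling lists in the comparisons of mutants. They were chosen on control samples of this study and are not independent evidence of direction.

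The comparison of NrKO with NrHet oocytes asks whether the maternal RNA store depends on Nr5a2, and 19 of 8952 genes changed (9 higher, 10 lower; 1062 at an unadjusted p under 0.05, with 448 expected by chance). Nav1, which binds microtubules, fell most, from 16.4 ± 6.97 TPM in 18 NrHet to 3.27 ± 2.05 in 12 NrKO oocytes (log2 fold change -1.98 ± 0.23, adjusted p = 6.39e-07, lower in 12 of 12). The zinc finger gene Zfp69 fell by 1.11 on the log2 scale and Rnpep, an aminopeptidase, by 0.81 (adjusted p = 0.0287 and 0.00343). Rises were smaller, with Dmwd at 0.80 ± 0.14 (62.6 ± 29.3 against 32.3 ± 18.0 TPM), the polarity GTPase Cdc42 at 0.77 ± 0.16 and Klhl12 at 0.54 ± 0.11. Of the 18 changed genes with a position, 5 lay within 10 Mb of Nr5a2 on chromosome 1 where 0.124 were expected (one-sided Fisher's exact test, adjusted p = 1.93e-06 over 18 comparisons). These were Nav1 at 1.24 Mb, Rnpep at 1.56 Mb, Elf3 at 1.58 Mb, Klhl12 at 2.35 Mb and Fam72a at 5.3 Mb. Elf3 was named after its values were seen. Among the lists, 34 oocyte and maternal genes and 28 polarity genes were higher as sets and 35 ribosome biogenesis genes lower (adjusted p = 0.0483 each; adjusted p = 0.504, 0.379 and 0.379 with an estimated correlation). Of their members 0, 1 (Cdc42) and 0 were called in limma, and 6, 1 and 7 adjusted over the list alone. Within dates, 8 genes passed on 5 June (6 NrKO, 12 NrHet) and 4 on 20 June (6 and 6), and all 19 kept their sign on both. Without a filter 3 genes passed, without a date factor 4, and against Nrpp oocytes 57 were higher and 50 lower. Between NrHet and Nrpp oocytes 3 genes fell, Zfp69 (-1.31 ± 0.27, adjusted p = 0.0454), Adamtsl1 (-0.61) and D7Ertd443e (-0.35).

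At the early 2-cell stage, embryos without maternal and zygotic Nr5a2 had lower levels of genes of the 2-cell burst, the wave of transcription that opens zygotic genome activation. Of 42 such genes tested, 28 fell and 0 rose, and 35 fell adjusted over the list alone, with a median log2 fold change of -1.32 (adjusted p = 2.17e-23; adjusted p = 0.0428 with an estimated correlation). Zscan4d, of a family that marks this burst, fell from 247 ± 174 TPM in 29 mz_NrHet to 62.6 ± 62.2 in 22 mz_NrKO embryos (log2 fold change -2.34 ± 0.48, adjusted p = 0.00103). With it fell Zscan4e (-3.56 ± 0.65), Zscan4b (-3.40), Zscan4a (-2.99), Zscan4f (-2.88 ± 0.60), Zscan4c (-2.58), Tdpoz8 (-2.79) and Tdpoz3 (-2.46). Members of these families share reads, so single values are uncertain, but the direction of each named Zscan4 gene held in every alternative run. Colgalt2, a collagen galactosyltransferase, fell from 9.26 ± 7.20 TPM to 0.0140 ± 0.0658, lower in 22 of 22 (-2.75 ± 0.29, adjusted p = 7.86e-12). It was not among the called genes within 10 Mb of Nr5a2, and DNA linked to the deleted allele beyond that window was not examined. Maternal transcripts that controls clear by this stage were higher as a set, with 21 of 346 falling-list genes up and 2 down (24 and 2 adjusted over the list alone; adjusted p = 2.51e-18, and adjusted p = 0.0428 with an estimated correlation). Among them Ccdc117 rose from 187 ± 122 to 395 ± 143 TPM (1.24 ± 0.20, adjusted p = 2.48e-05, higher in 21 of 22), and Nfrkb, a subunit of the INO80 chromatin remodeller, by 1.15 on the log2 scale. Other rises were the stress-induced mTORC1 inhibitor Ddit4 (1.18 ± 0.23; 190 ± 83.2 against 95.5 ± 68.3 TPM), Mtfr2 (1.47), Ttc34 (1.34) and Phax (1.25), a factor for export of small nuclear RNA. Hmga1b, a chromatin protein gene, rose by 2.50 against mz_NrHet, yet its log2 fold change was -0.33 against mz_Nrpp.

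Other lists at E2C had calls in mz_NrKO as well. In mitosis 7 of 66 genes fell, among them Zwint (-0.71 ± 0.14), a kinetochore protein, and the kinase Aurkb (-0.62). Adjusted over the list alone 10 fell, and the set was lower (adjusted p = 0.00978; adjusted p = 0.985 with an estimated correlation). The rising list of 2204 genes had 311 down and 7 up (405 and 15 adjusted over the list alone; adjusted p = 4.76e-05, and adjusted p = 0.795 with an estimated correlation). No other list was called as a set with camera. With fry 3 lists passed, all lower, the 2-cell burst (adjusted p = 4.63e-05), telomere genes (0.0206) and the rising list (0.0262). Oocyte and maternal genes had 3 of 34 up, with Zar1 (0.55) and Plat (0.55) among them, and 2 down. The falls were Cnot6l (-0.38), a deadenylase subunit, and Dppa3 (-0.26). Polarity, adhesion and Hippo genes had 2 of 36 up (Ctnnb1, 0.56, and Llgl1, 0.55) and 3 down, including Scrib (-1.16) and Myh10 (-1.10). Falls numbered 3 of 29 in telomere genes (Zscan4c, Atrx, -0.42, and Hnrnpa1, -0.31) and 2 of 48 in ribosome biogenesis (Nop16, -1.43, and Nop56, -0.63). They were 2 of 62 in oxidative phosphorylation (Ndufv1, -1.01, and Atp5b, -0.35) and 2 of 50 in DNA replication (Dbf4, -0.34, and Pcna, -0.32). A single fall was seen in cholesterol synthesis (Mvk, -1.42), pluripotency (Tet2, -0.83) and DNA repair (Blm, -0.38). Ddit4 rose and Sesn2 (-1.07) fell in both the p53 and stress lists. In limma 0 of 18 trophectoderm genes and 0 of 7 liver and steroid targets of Nr5a2 passed. Adjusted over the list alone, the changed genes numbered 6 in oocyte and maternal genes, 7 in polarity, 6 in telomere, 7 in p53 and 3 in stress genes. Also adjusted over the list alone, there were 1 each in repair, replication, cholesterol and pluripotency, 2 each in ribosome biogenesis and oxidative phosphorylation, and 0 in trophectoderm and liver targets.

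In all, 674 of 13040 genes passed for mz_NrKO at E2C, 587 lower and 87 higher (2554 at an unadjusted p under 0.05), and 310 changed at least 2-fold. The median log2 fold change of all genes was -0.088. With median-of-ratios scaling it was -0.009, with 555 lower and 360 higher. A single library stood apart. It was mz_NrKO replicate 1, which had the lowest TPM sum (814735), Esrrb at 1250 TPM against 15.5 ± 6.62 in the other 21, Zscan4d at 2.13 TPM and Ccdc117 at 123 TPM. Without it 501 genes were lower and 367 higher, 564 of them shared. Against mz_Nrpp the count was 233 (194 lower), 133 of them shared. Within dates, 293 genes passed on 1 August (12 mz_NrKO, 12 mz_NrHet) and 356 on 7 November (8 and 7), and 99.4% and 96.4% of the 674 had the pooled sign. On 14 November (2 and 3) 0 genes passed in limma (538 at an unadjusted p under 0.05), and 84.1% had the pooled sign.

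**Figure D3:**
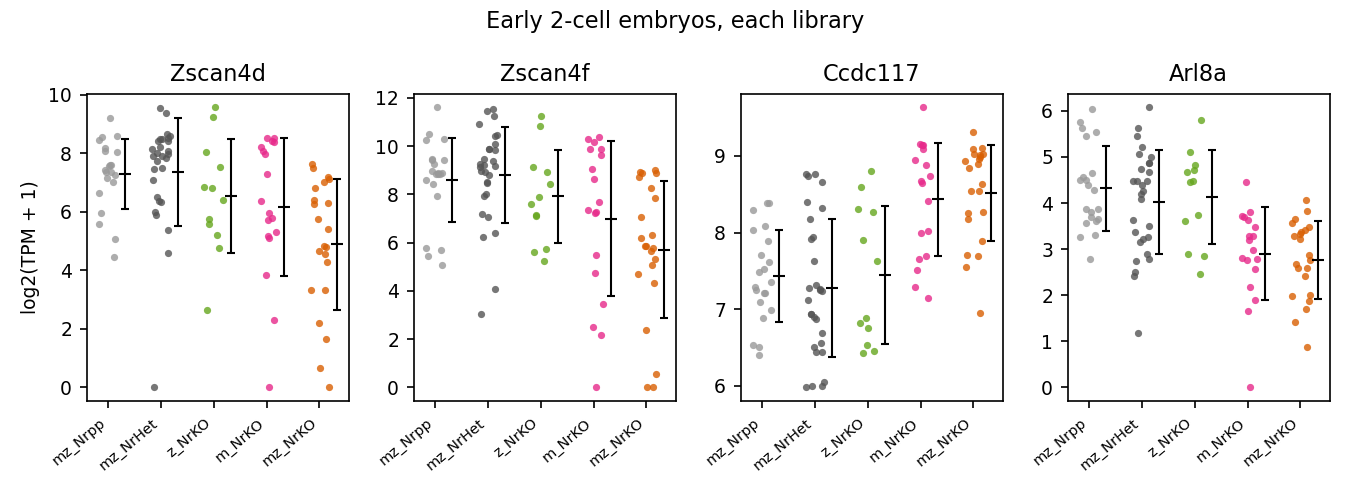
Each point is an E2C library and shows log2(TPM + 1) of Zscan4d, Zscan4f, Ccdc117 and Arl8a in mz_Nrpp, mz_NrHet, z_NrKO, m_NrKO and mz_NrKO embryos, with the mean and SD of each group. Zscan4d falls from 247 ± 174 TPM in mz_NrHet to 62.6 ± 62.2 in mz_NrKO, and Ccdc117 rises from 187 ± 122 to 395 ± 143 TPM. Arl8a lies 1.69 Mb from Nr5a2, so its fall may come from DNA linked to the deleted allele.

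Embryos lacking Nr5a2 only from the oocyte (m_NrKO) or only after fertilization (z_NrKO) were each compared with mz_NrHet at E2C, and not with each other. In 18 m_NrKO embryos 32 genes changed against 29 mz_NrHet (12 higher, 20 lower; 1738 at an unadjusted p under 0.05). Colgalt2 fell to 2.48 ± 3.48 TPM (log2 fold change -1.72 ± 0.31, adjusted p = 0.00213), and Arl8a, a lysosomal GTPase, from 20.1 ± 15.0 to 7.96 ± 4.94 TPM (-1.40 ± 0.27, adjusted p = 0.00233). The kinase Prkch (-1.91 ± 0.42) and Rnpep (-0.78 ± 0.16) also fell. Arl8a and Rnpep lie 1.69 and 1.56 Mb from Nr5a2, so DNA linked to the deleted allele cannot be told apart from an effect of the loss there. They were 2 called genes within 10 Mb where 0.226 were expected (one-sided Fisher's exact test, adjusted p = 0.192). Colgalt2 was not in that window, and linked DNA beyond 10 Mb was not examined. Ccdc117 rose to 387 ± 182 TPM (1.15 ± 0.22, adjusted p = 0.00224, higher in 15 of 18), as did Ttc34 (1.59), Phax (1.17) and Prkab1 (0.75), a subunit of the energy sensor AMPK. Genes of the 2-cell burst were lower as a set (median -0.84, adjusted p = 3.41e-13) and the falling list higher (adjusted p = 4.95e-12), and both had adjusted p = 0.301 with an estimated correlation. Of their members 0 of 42 and 4 of 346 were called in limma, and 11 and 19 changed adjusted over the list alone. Mitosis genes were lower as a set (adjusted p = 0.00185; adjusted p = 0.867 with an estimated correlation), 1 of 66 being called (Esco2, -0.43) and 2 adjusted over the list alone. The m_NrKO count rested on the processing. It was 392 with median-of-ratios scaling, all 32 genes among them, and 409 without mz_NrKO replicate 1. Within dates, 166 genes passed on 1 August (7 m_NrKO, 12 mz_NrHet) and 439 on 7 November (4 and 7). On 14 November (7 and 3) 0 passed in limma (819 at an unadjusted p under 0.05). At least 93.8% of the 32 kept their sign on each of 3 dates. These 32 include 0 burst genes, and the burst set was not tested within dates. Its level was uneven between m_NrKO embryos. Zscan4d lay between 0 and 81.5 TPM in replicates 1 to 7 and between 51.36 and 366.7 TPM in replicates 8 to 18. In mz_NrHet it lay between 0 and 745.7 TPM.

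In 12 z_NrKO embryos at E2C, 0 genes passed in limma, with 701 at an unadjusted p under 0.05 where 652 were expected. The 2-cell burst was lower as a set (median -0.62, adjusted p = 3.56e-11). Oocyte and maternal genes (adjusted p = 3.17e-05), the falling list (adjusted p = 0.000343) and oxidative phosphorylation (adjusted p = 0.0495) were higher. Of their members 0 were called in limma and 0 adjusted over the list alone, and each set had adjusted p = 0.756 with an estimated correlation. The direct test of mz_NrKO against m_NrKO gave 0 genes in limma (918 at an unadjusted p under 0.05). The burst genes were lower in mz_NrKO as a set (adjusted p = 0.0018; adjusted p = 0.959 with an estimated correlation; 0 members called, 0 adjusted over the list alone). Against mz_Nrpp, 18 genes passed in z_NrKO. The 2 controls differed in 35 genes. Mt1, the metallothionein gene, rose from 0.920 ± 1.83 TPM in 21 mz_Nrpp to 24.6 ± 10.7 in 29 mz_NrHet embryos (4.13 ± 0.21, adjusted p = 2.23e-33, higher in 29 of 29). Kif18b, a mitotic kinesin, rose too (0.93 ± 0.15), and Hmga1b fell (-2.82 ± 0.65). The burst list was higher in mz_NrHet as a set (adjusted p = 0.00675; adjusted p = 0.964 with an estimated correlation; 0 members called, 0 adjusted over the list alone). With median-of-ratios scaling 52 genes were higher and 52 lower. Within dates 34, 2 and 31 genes separated the controls.

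At the late 2-cell stage few genes passed with the date in the fit, and all but 1 of them were lower. In 10 mz_NrKO embryos 18 genes fell and 0 rose against 7 mz_DHet in limma (1143 at an unadjusted p under 0.05, 707 expected). All 10 mz_NrKO were dated 8 March 2022, but only 2 mz_DHet were, and the other 5 were dated 22 May. The test with date in the fit thus leans on those 2 controls, while the group means in TPM cover both dates. Cers2, a ceramide synthase, fell from 177 ± 53.5 to 33.3 ± 16.2 TPM (log2 fold change -2.49 ± 0.40, adjusted p = 0.00194), and the tousled-like kinase Tlk2 from 164 ± 38.8 to 43.4 ± 34.0 TPM (-2.59 ± 0.47, adjusted p = 0.0056). Tulp1, of the tubby-like family, fell from 31.9 ± 18.3 to 0.672 ± 0.857 TPM (-3.86 ± 0.68, adjusted p = 0.00539), and Ajuba, a LIM protein of Hippo signalling, from 109 ± 21.2 to 32.4 ± 19.5 TPM (-2.35 ± 0.53, adjusted p = 0.0447). Each was lower in 10 of 10. In 6 mz_DKO embryos 20 genes fell and 0 rose in limma (1181 at an unadjusted p under 0.05). Tulp1 was listed at 0 in all 6, and Tlk2 stood at 38.9 ± 23.5 TPM (-2.50 ± 0.44, adjusted p = 0.00271). The phosphatase subunit Ppp1r16b fell to 3.44 ± 3.52 from 26.4 ± 11.3 TPM (-3.19 ± 0.58), and Cdc7, a kinase that fires replication origins, by 1.92 on the log2 scale (adjusted p = 0.0365). Zygotic loss alone left 13 genes lower and 1 higher in 6 z_NrKO against 7 z_NrHet embryos (1207 at an unadjusted p under 0.05). There Ppp1r16b fell from 74.1 ± 29.7 to 8.66 ± 4.72 TPM (-2.95 ± 0.54, adjusted p = 0.00796), and Igf2r, the receptor that clears Igf2, from 162 ± 36.2 to 49.7 ± 16.1 TPM (-1.76 ± 0.34, adjusted p = 0.00885). Oaz3, an antizyme of polyamine synthesis, was the gene that rose, from 2.88 ± 3.63 to 28.9 ± 12.1 TPM (3.38 ± 0.64, adjusted p = 0.00885). In 10 mz_EKO embryos 0 genes passed in limma (947 at an unadjusted p under 0.05).

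Gene lists at L2C were called as sets with few members called. In mz_NrKO the rising list of 2830 genes was lower (median -0.28, 14 down and 0 up, 32 and 0 adjusted over the list alone; adjusted p = 3.35e-13, and adjusted p = 0.451 with an estimated correlation). The falling list (adjusted p = 2e-10), the 2-cell burst (median 0.64, adjusted p = 0.00785) and oocyte genes (adjusted p = 0.0158) were higher. Ribosome biogenesis (adjusted p = 0.000226) and oxidative phosphorylation (adjusted p = 0.00293) were lower. In these 5 sets 0 members were called in limma and 0 adjusted over the list alone, with adjusted p = 0.596 with an estimated correlation for each. In mz_EKO the same sets except oocyte genes, and the rising list, were called in the same directions (adjusted p = 8.75e-07 for rising, 2.78e-06 for falling, 0.00268 for the burst, 0.00131 for ribosome biogenesis and 8.12e-05 for oxidative phosphorylation). A lower mitosis set was called as well (0.0212). Both mutants lean on the same 2 mz_DHet embryos of 8 March 2022, so their shared sets are not separate findings. There 0 members passed in limma, 0 adjusted over the list alone, and the adjusted p = 0.62 with an estimated correlation for ribosome biogenesis and 0.502 for the others. No list passed in mz_DKO. In z_NrKO the burst was higher as a set (median 0.42, adjusted p = 0.00231; adjusted p = 0.836 with an estimated correlation; 0 members called, 0 adjusted over the list alone). Markers of cumulus and granulosa cells had 5 tested members and no call (adjusted p = 0.619 in mz_NrKO, 0.866 in mz_EKO, 0.754 in mz_DKO and 0.502 in z_NrKO). In mz_EKO their median of -0.18 and the direction of the test differed in sign. Counts at L2C depended on single choices. UMI reads called 0 genes in mz_NrKO, 2 in mz_DKO and 2 in z_NrKO, and a fit without the date factor called 1527 in mz_NrKO (901 higher, 626 lower) and 296 in mz_EKO. The 18 genes of mz_NrKO became 4 without mz_DHet replicate 6 and 8 without replicate 7. The 20 of mz_DKO became 11 without mz_DHet replicate 3 and 13 without replicate 7. In UMI reads the burst was not called as a set (adjusted p = 0.265 in mz_NrKO, 0.175 in mz_EKO and 0.28 in z_NrKO), nor were ribosome biogenesis (0.105) and mitosis (0.893) in mz_EKO. The other 5 sets of mz_NrKO and 3 of mz_EKO were called in the same directions with the preset correlation. On 8 March 2022, with 2 mz_DHet embryos, 0 of 14147 genes passed in limma in mz_NrKO or mz_DKO (686 and 639 at an unadjusted p under 0.05). On 22 May 2022 (2 mz_DKO, 5 mz_DHet) 0 passed in mz_DKO in limma (1194 at an unadjusted p under 0.05), and all 20 genes of mz_DKO kept their sign on both dates.

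At the 4-cell stage 88 genes changed in 5 mz_NrKO embryos against 6 mz_DHet (34 higher, 54 lower; 1477 at an unadjusted p under 0.05, 652 expected). In 10 mz_DKO embryos 336 changed (34.8% of them higher, 219 lower). Tead4 (ENSMUSG00000030353.15, chromosome 6, 128224288 to 128300823), the transcription factor that trophectoderm formation requires, fell from 249 ± 49.4 TPM to 30.1 ± 16.5 in mz_NrKO (log2 fold change -2.69 ± 0.50, adjusted p = 0.00924) and 29.7 ± 19.2 in mz_DKO (-3.46 ± 0.40, adjusted p = 1.13e-05), lower in every library of both. In UMI reads its fall in mz_DKO did not pass. Ppp1r16b fell from 52.5 ± 9.00 to 4.32 ± 3.10 TPM in mz_NrKO (-3.56 ± 0.54, adjusted p = 0.00138), and Tlk2 from 107.9 ± 44.7 to 15.0 ± 9.79 TPM (-2.90 ± 0.39, adjusted p = 0.00046). The receptor S1pr2 (-4.13), the ETS factor Etv6 (-3.60), Rflnb (-3.52) and Tulp1 (-3.27) fell as well. Rises in mz_NrKO were Rln3, a relaxin peptide (44.9 ± 21.9 against 4.96 ± 5.90 TPM, 2.98 ± 0.64, adjusted p = 0.0236), the homeobox gene Cphx1 (3.20), Erfe (2.91), the stress kinase Mapk13 (2.36) and S1pr5 (2.36). Of 42 genes of the 2-cell burst 1 rose, the arginase Arg2 (2.40 ± 0.49, higher in 3 of 5). Adjusted over the list alone 5 rose, and the set was higher (adjusted p = 0.0128; adjusted p = 0.877 with an estimated correlation).

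In mz_DKO at 4C the nodal cofactor Tdgf1 (-3.25 ± 0.65, adjusted p = 0.00468), the homeobox gene Mixl1 (-3.75), Cdc25b (-2.72), which activates cyclin-dependent kinases, and Tead1 (-2.10) fell. The water channel Aqp3 (26.6 ± 26.4 against 0.290 ± 0.317 TPM, 3.43 ± 0.73, adjusted p = 0.0081), the claudins Cldn6 (2.49 ± 0.42) and Cldn7 (1.51 ± 0.40), and the Hippo effector Wwtr1 (1.27 ± 0.34) rose. For the 2-cell burst 5 of 42 genes rose, Arg2 (2.54 ± 0.39, 84.8 ± 45.2 TPM) and Usp17ld (2.53) among them. Adjusted over the list alone 8 rose and 1 fell, and the set was higher (adjusted p = 0.00765; adjusted p = 0.944 with an estimated correlation). No gene passed in 4 mz_EKO embryos (0 in limma, 803 at an unadjusted p under 0.05). With UMI reads 17 genes passed in mz_NrKO, 13 of them shared, and 125 in mz_DKO. The mz_NrKO count was 27 without mz_NrKO replicate 2 and 31 without replicate 1, and 54, 42 and 32 without mz_DHet replicates 4, 5 and 6. The mz_DKO count was 215, 218, 208 and 223 without mz_DHet replicates 3, 4, 5 and 6. In UMI reads the burst was not called as a set at 4C (adjusted p = 0.361 in mz_NrKO and 0.151 in mz_DKO). In those reads, with the preset correlation, ribosome biogenesis was lower in mz_EKO (0.021) and polarity genes were higher in mz_DKO (0.033). On 17 June 2022, 22 genes passed in mz_NrKO (2 against 5) and 347 in mz_DKO (9 against 5), and all 88 and all 336 kept their sign. On 22 May 2022, with 1 mz_DHet embryo, all 88 and 92.3% of the 336 did.

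The 8-cell stage carried the largest counts, 3075 of 10876 genes in 10 mz_NrKO against 21 mz_DHet embryos (1532 higher, 1543 lower; 4234 at an unadjusted p under 0.05, 544 expected), 1548 of them at least 2-fold. Cdx2 (ENSMUSG00000029646.3, chromosome 5, 147300805 to 147307270), the transcription factor of the trophectoderm, fell from 92.8 ± 68.5 to 26.2 ± 76.2 TPM (log2 fold change -3.86 ± 0.62, adjusted p = 3.79e-06, lower in 9 of 10). Crip2 (ENSMUSG00000006356.10, chromosome 12, 113140236 to 113145506), a LIM-domain gene, fell from 562 ± 210 to 136 ± 360 TPM (-4.43 ± 0.42, adjusted p = 4.61e-11), and the ferrireductase Steap3 from 59.9 ± 22.1 to 10.4 ± 27.7 TPM (-4.00 ± 0.45). Other large falls were Psme1 (-3.70), an activator of the proteasome, Plk5 (-3.62), the threonine dehydrogenase Tdh (-3.57) and Actn2 (-3.57). Rln3 (ENSMUSG00000045232.4, chromosome 8, 84042929 to 84045000) rose from 1.82 ± 3.62 to 47.4 ± 38.0 TPM (4.05 ± 0.50, adjusted p = 1.6e-08). Cyp26a1, which degrades retinoic acid, rose to 36.7 ± 57.96 TPM (3.56 ± 0.51) and the ephrin Efna3 to 95.9 ± 92.8 TPM (3.49 ± 0.43). Obox8 (4.02) and Tdpoz4 (3.67) rose as well, with values that are uncertain because their families share reads.

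The wide spread of Cdx2 and Crip2 in mz_NrKO came from replicate 1, which did not share these changes. Its levels were 243 TPM for Cdx2 (2.13 ± 2.38 in the other 9), 1160 for Crip2 (22.7 ± 24.5), 284 for Klf5 (116 ± 38.9) and 0 for Rln3 (52.6 ± 36.3), Obox8 and Cyp26a1. Without that library 3585 genes changed (1825 higher, 1760 lower). Without a date factor 2256 genes passed and with UMI reads 2272 (1356 higher, 916 lower), or 2722 without the UMI library labelled mz_DHet replicate 12. Without a filter 1918 were higher and 1291 lower. On 8 March 2022 (6 mz_NrKO, 15 mz_DHet) 3209 genes passed and 3074 of the 3075 kept their sign. On 15 July 2022 (3 and 4) 556 passed and 95.2% kept it. On 23 February 2022, whose only mz_NrKO embryo was replicate 1, 42.8% did.

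**Figure D4:**
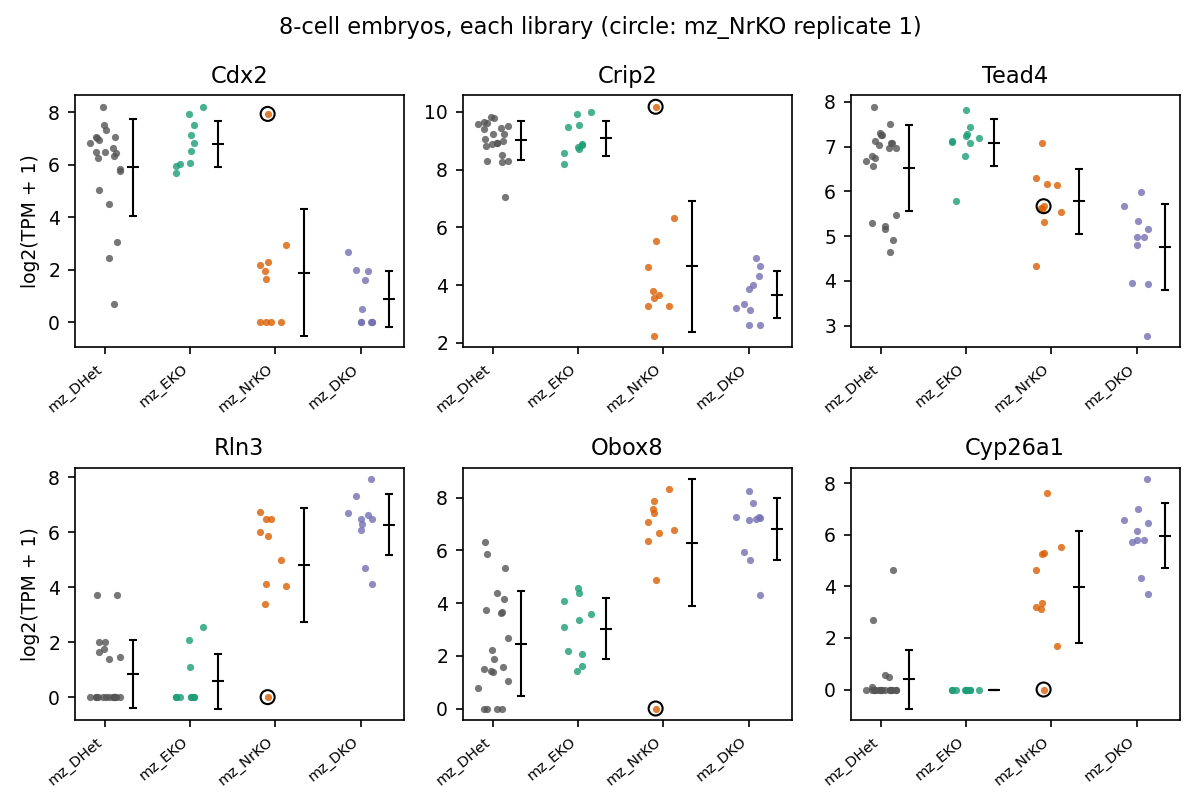
Each point is an 8C library and shows log2(TPM + 1) of Cdx2, Crip2, Tead4, Rln3, Obox8 and Cyp26a1 in mz_DHet, mz_EKO, mz_NrKO and mz_DKO embryos, with the mean and SD of each group and a circle around mz_NrKO replicate 1. That library has Cdx2 at 243 TPM and Rln3 at 0, against 2.13 ± 2.38 and 52.6 ± 36.3 TPM in the other 9 mz_NrKO libraries.

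Trophectoderm genes were lower as a set in mz_NrKO at 8C, where 12 of 23 fell, 3 rose and 8 were not called (14 and 3 adjusted over the list alone; median -0.99, adjusted p = 0.00045, and adjusted p = 0.353 with an estimated correlation). Klf5, a transcription factor that early lineages require, fell from 419 ± 134 to 132 ± 64.6 TPM (-1.60 ± 0.17, adjusted p = 5.96e-10, lower in 10 of 10). Aqp3 fell from 487 ± 224 to 94.4 ± 115 TPM (-2.71 ± 0.39), and Tinagl1 (-2.90) and Dppa5a (-1.36) fell too. Genes of the 2-cell burst were higher as a set, 12 of 24 up and 1 down (14 and 1 adjusted over the list alone; adjusted p = 6.94e-05, and adjusted p = 0.353 with an estimated correlation). Arg2 stood at 54.4 ± 52.4 against 4.90 ± 6.18 TPM (2.78 ± 0.51, adjusted p = 4.2e-05, higher in 7 of 10), and Usp17ld rose by 2.38 on the log2 scale. In UMI reads both sets were called in the same directions with the preset correlation (adjusted p = 3.47e-08 and 0.0292). No other list was called as a set with camera. With fry 7 lists passed. Besides the trophectoderm (adjusted p = 2.08e-05) and the burst (4.66e-05), oocyte genes (0.00379) and the rising list (0.0312) were higher. The liver and steroid targets (0.00016), the falling list (0.0309) and pluripotency genes (0.0334) were lower. In the pluripotency list Klf4 fell from 48.6 ± 25.8 to 8.12 ± 3.73 TPM (-2.12 ± 0.27, adjusted p = 5.5e-08), as did Tdgf1 (-2.43), Tfcp2l1 (-1.67) and Pou5f1 (-0.47). In that list 5 of 22 rose and 5 fell (5 and 6 adjusted over the list alone). Primitive endoderm had 3 of 12 up, Pdgfra (1.99) and Gata4 (1.46) among them, and 2 down, Dab2 (-2.59) and Col4a1 (-1.02), with the same counts adjusted over the list alone. Polarity and Hippo genes had 2 of 36 up and 10 down, also adjusted over the list alone (adjusted p = 0.0631). Wwtr1 rose from 37.7 ± 15.7 to 140 ± 60.2 TPM (1.75 ± 0.21, adjusted p = 1.52e-08), and Pard6b (-1.69), Prkcz (-1.45) and Tead2 (-2.22) fell.

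Cell cycle and metabolic lists went both ways in mz_NrKO at 8C. Mitosis had 12 of 66 up and 8 down (13 and 8 adjusted over the list alone). Cdk1, the kinase of mitotic entry, fell from 823 ± 206 to 269 ± 67.0 TPM (-1.61 ± 0.18, adjusted p = 1.17e-09), and the condensin gene Ncapg rose (1.05). DNA replication had 5 of 50 up (Prim1, 0.79) and 8 down (Rrm2, -1.17), the same adjusted over the list alone. DNA repair had 14 of 80 up (Bard1, 1.05) and 12 down (Parp1, -1.35), again the same alone. Telomere genes had 3 of 29 up (Rif1, 0.82) and 5 down (Acd, -0.60), or 2 and 5 adjusted over the list alone. Targets of p53 had 5 of 27 up (Plk2, 1.99, and Btg2, 1.69) and 2 down (Tigar, -0.76), or 4 and 1. Cholesterol synthesis had 3 of 25 up, with the regulator Srebf2 at 1.30, and 7 down, with the squalene synthase Fdft1 at -1.64, the same adjusted over the list alone. Ribosome biogenesis had 4 of 49 up (Utp3, 1.08) and 5 down (Polr1a, -0.97), or 3 and 5 alone. Oxidative phosphorylation had 3 of 71 up (Ndufv2, 0.85) and 5 down (Ndufa8, -1.10), or 3 and 1 alone, and stress genes 2 of 21 up (Asns, 1.72) and 3 down (Xbp1, -1.46), the same alone. Of 6 liver and steroid targets of Nr5a2, 3 fell and 0 rose, Ccne1 (-1.35 ± 0.17, adjusted p = 5.46e-08), Scarb1 (-1.50) and Pou5f1, the same alone (adjusted p = 0.108). Oocyte genes had 3 of 9 up (Dppa3, 0.77, and Zp3, 1.36) and 1 down (Khdc3, -3.03; 205 ± 204 against 928 ± 330 TPM), the same alone. The rising list had 8 of 44 up and 3 down (8 and 2 alone) and the falling list 5 of 94 up and 22 down (the same alone). Markers of blood, sperm, oviduct epithelium and the Y chromosome had at most 4 tested members at any stage and were not tested as sets, nor were cumulus markers within a stage outside L2C. In the joint fits across stages 6 cumulus markers gave adjusted p = 0.314 against L2C and 0.358 against 4C.

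Loss of Esrrb changed 1 gene at 8C in 10 mz_EKO embryos, Esrrb itself (257 at an unadjusted p under 0.05, 544 expected), and its call was lost without a date factor (-1.48). As sets, oxidative phosphorylation was lower (adjusted p = 0.00717) and ribosome biogenesis higher (adjusted p = 0.0238) with 0 members called in limma, 0 adjusted over the list alone, and adjusted p = 0.907 with an estimated correlation for both. In UMI reads oxidative phosphorylation was called as lower (adjusted p = 0.0421), ribosome biogenesis was not called (0.22), and pluripotency genes were higher (0.0271). The direct contrast of mz_NrKO with mz_EKO gave 2466 genes (1182 higher, 1284 lower). Steap3 (-4.71), Crip2 (-4.60) and Cdx2 (-4.51 ± 0.74, 26.2 ± 76.2 against 130 ± 83.7 TPM) were lower. Rln3 (4.46) and Efna3 (4.29) were higher, and Cyp26a1 was listed at 0 in all 10 mz_EKO libraries. Burst genes rose in 14 of 24 and fell in 1, and trophectoderm genes fell in 12 of 23 and rose in 2 (15 changed in each list adjusted over the list alone; adjusted p = 0.000126 each, and adjusted p = 0.211 with an estimated correlation). With fry 7 lists passed, the same 7 and in the same directions as in mz_NrKO against mz_DHet.

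Loss of both receptors changed 3669 genes at 8C (2059 higher, 1610 lower; 4614 at an unadjusted p under 0.05), 1997 at least 2-fold. In 10 mz_DKO embryos Cdx2 fell to 1.38 ± 1.90 TPM (log2 fold change -5.26 ± 0.63, adjusted p = 3.42e-09, lower in 10 of 10) and Crip2 to 13.7 ± 8.29 (-5.25 ± 0.42). Slc25a41 (ENSMUSG00000011486.14, chromosome 17, 57032773 to 57041654), a mitochondrial carrier, fell from 35.9 ± 14.2 to 1.48 ± 2.98 TPM (-4.38 ± 0.31, adjusted p = 2.97e-15). Tnfsf13b, a cytokine gene, was listed at 0 in all 10. Cyp26a1 rose to 85.4 ± 77.4 TPM (5.57 ± 0.51), Rln3 to 96.5 ± 64.9 (5.30) and the secreted phosphoprotein Spp1 from 3.35 ± 2.75 to 124 ± 82.6 (5.12 ± 0.53, adjusted p = 1.08e-10). So did the homeobox gene Gsc from 11.3 ± 11.8 to 237 ± 126 (4.52) and the interferon-induced Ifitm3 to 74.1 ± 39.1 (4.79). Trophectoderm genes had 14 of 23 down and 3 up (14 and 5 adjusted over the list alone; median -1.33, adjusted p = 1.21e-05). Tinagl1 (-4.31), Klf5 (-1.90) and Tead4 (-2.01 ± 0.24, 31.0 ± 17.0 against 109 ± 56.7 TPM) were among the falls. The 2-cell burst had 17 of 24 up and 1 down (18 and 1 adjusted over the list alone; adjusted p = 4.36e-06), with Usp17ld (3.25) and Tcstv1 (2.95) among the rises. Both sets had adjusted p = 0.197 with an estimated correlation. With fry 6 lists passed. Besides these 2 (adjusted p = 4.25e-08 each), oocyte genes (0.000543), stress genes and the rising list (0.0134 each) were higher and the liver and steroid targets (0.000185) lower. Further named rises were Wwtr1 (2.58), Prdm14 (2.67), a regulator of naive pluripotency, Gata4 (2.21), Chac1 (3.83), an enzyme of the unfolded protein response, and Jun (1.89). Khdc3 (-3.78), the Hippo kinase Lats2 (-2.08), Klf4 (-1.77) and Nanog (-1.19) fell. On 8 March 2022, 3743 genes passed and all 3669 kept their sign. On 23 February 2022, with 1 mz_DKO embryo, 81.2% did.

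Adding the loss of Esrrb to that of Nr5a2 moved few genes past the test at 8C. Between mz_DKO and mz_NrKO 16 genes differed (4 higher, 12 lower; 1092 at an unadjusted p under 0.05). Slc25a41 was lower at 1.48 against 10.8 TPM (-2.62 ± 0.37, adjusted p = 3.95e-05), Aacs, which activates acetoacetate for lipid synthesis, at 12.7 against 38.6 TPM (-1.81 ± 0.30). Tead4 was lower at 31.0 ± 17.0 against 60.4 ± 31.5 TPM (-1.43 ± 0.29, adjusted p = 0.012), and Spp1 was higher (3.11). As sets, trophectoderm genes were lower (adjusted p = 0.0154) and stress genes higher (adjusted p = 0.0143; adjusted p = 0.855 with an estimated correlation for both). These set values, and those beyond the sum, include mz_NrKO replicate 1. Cdx2, a trophectoderm gene, stood at 243 TPM in that library, which adds to the difference for that gene. Burst genes were higher and oxidative phosphorylation lower (adjusted p = 0.0406 each, and adjusted p = 0.975 with an estimated correlation). In these 4 sets 1, 0, 0 and 0 members were called in limma, and 1, 1, 0 and 0 adjusted over the list alone. Only 8 genes passed without mz_NrKO replicate 1, 7 of them shared, and 3 with UMI reads (6 without the UMI library labelled mz_DHet replicate 12). None of the 4 sets was called in UMI reads (adjusted p = 0.163 for trophectoderm genes and oxidative phosphorylation, 0.279 for stress and 0.989 for burst genes), and the first 2 had the opposite direction there. Ribosome biogenesis was lower in UMI reads alone (adjusted p = 0.002). On 8 March 2022 5 genes passed, and all 16 kept their sign. The test of mz_DKO beyond the sum of the single losses called 4 genes, all lower: Slc25a41 (-2.53 ± 0.47, adjusted p = 0.0137), Aacs (-1.95 ± 0.38), Tead4 (-1.74 ± 0.37, adjusted p = 0.0444) and Strada (-1.22 ± 0.24), an activator of the kinase Lkb1. Trophectoderm genes were lower (adjusted p = 0.00376) and stress genes higher (adjusted p = 0.0121) beyond the sum, with adjusted p = 0.55 with an estimated correlation for both. Of their members 1 and 0 were called in limma, and 1 and 0 adjusted over the list alone. Tead4 was not called there without mz_NrKO replicate 1 or in UMI reads (-0.17). With no date factor, with UMI reads, on a single date and with a block for the library number 0 of the 4 passed in limma. In UMI reads neither set was called beyond the sum (adjusted p = 0.518 for trophectoderm, in the opposite direction, and 0.375 for stress genes). Only there were ribosome biogenesis lower (0.000572) and oxidative phosphorylation higher (0.0173).

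Changes in mz_NrKO and mz_DKO at 8C followed each other across genes. Both groups had 1218 genes higher and 1116 lower, where independent calls would give 290 and 228.4, and 0 genes were called in opposite directions. Across genes, which are not independent replicates and share the mz_DHet controls, log2 fold changes correlated with r = 0.869 and rho = 0.814. Where each mutant was set against a different part of the controls, the median r was 0.795 (0.734 to 0.817). Simulated groups without a shared effect reached at most 0.441. They were built on the fitted levels of the same controls, so they lack the error of shared controls and give no chance value for r. For mz_NrKO and mz_EKO r was -0.0339 and rho -0.0524. With different parts of the controls the median r was -0.131. Groups simulated in the same way gave a median of -0.0662 and at most 0.471, with the same limit.

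**Figure D5:**
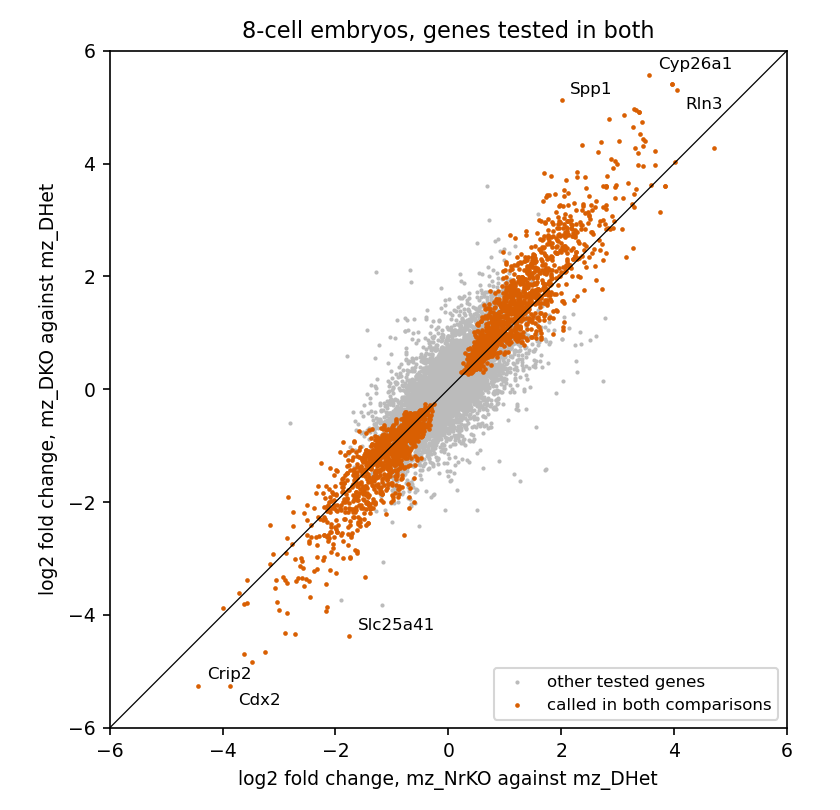
Each point is a gene tested at 8C, with the log2 fold change against mz_DHet in mz_NrKO on the x axis and in mz_DKO on the y axis, and the line marks equal change. The correlation is r = 0.869, Cdx2 lies at -3.86 and -5.26, and Cyp26a1 at 3.56 and 5.57.

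The effect of Nr5a2 loss was compared between stages in joint fits, which ask whether a gene's response at 8C differs from that at an earlier stage. A gene near 0 TPM at the earlier stage cannot fall there, and the earlier levels were not weighed, so a lower effect at 8C does not show a need for Nr5a2 at that stage alone. Against L2C 317 of 17686 genes differed (189 higher, 128 lower at 8C). Cdx2 (-3.86 ± 0.91, adjusted p = 0.0109), the hypoxia factor Epas1 (-4.23 ± 0.78, adjusted p = 0.00132), Ass1 (-3.73), an enzyme of the urea cycle, and Crip2 (-3.45) had lower effects at 8C. The nucleoporin-like Nup62cl (5.30 ± 1.17, adjusted p = 0.00646) and Rln3 (3.89) had higher ones. Against 4C 265 genes differed (130 higher, 135 lower). Aqp3 (-5.37 ± 1.00, adjusted p = 0.000667), Crip2 (-5.32 ± 0.86), Bok (-4.43), a relative of the Bcl-2 proteins, Cdx2 (-3.87 ± 0.90) and the adhesion gene Cdh1 (-2.46) had lower effects at 8C, and Ppp1r16b (4.46 ± 0.63, adjusted p = 2.8e-06) a higher one. Trophectoderm genes had lower effects at 8C than at 4C as a set (4 of 29 lower, 4 lower and 2 higher adjusted over the list alone; adjusted p = 0.00307, and adjusted p = 0.463 with an estimated correlation). So did polarity genes (1 of 40 higher and 3 lower, 1 and 5 adjusted over the list alone; adjusted p = 0.013) and DNA replication (1 of 50 lower, 2 alone; adjusted p = 0.0172; adjusted p = 0.468 with an estimated correlation for both). Against L2C, trophectoderm (2 lower) and polarity genes (1 higher) had lower set effects. Ribosome biogenesis (1 higher) and oxidative phosphorylation (2 higher) had higher ones (for the 4 sets, 6, 3, 1 and 2 members adjusted over the list alone; adjusted p = 0.035 each, and adjusted p = 0.682 with an estimated correlation). Without the libraries standing apart 582 genes differed against L2C and 583 against 4C, among them 305 of the 317 and all 265. Stage and date could not be separated in part, since few dates were shared between stages.

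The authors' deposited table of fold changes, made on counts with DESeq2 and with the Nrpp control at the early stages, was set beside the present calls. For mz_NrKO at 8C the authors' deposited table called 3506 genes (2260 higher, 1246 lower), of which 2352 were among the 3075, and log2 fold changes correlated across genes with r = 0.939. For mz_DKO at 8C the authors' deposited table called 3959 genes, 2975 of them shared (r = 0.954), and for mz_EKO at 8C 2, with 1 shared (r = 0.793). At 4C the authors' deposited table called 550 genes in mz_NrKO (82 shared, r = 0.83), 875 in mz_DKO (314 shared, r = 0.892) and 84 in mz_EKO (0 shared). At L2C the authors' deposited table called 75 genes higher and 33 lower in mz_NrKO (11 shared), 469 in mz_DKO (182 higher, 287 lower; 17 shared), 50 in mz_EKO (0 shared) and 224 in z_NrKO (77 higher, 147 lower; 14 shared). Against mz_Nrpp at E2C the authors' deposited table called 786 genes in mz_NrKO where limma called 233 (140 shared, r = 0.767) and 198 in m_NrKO (20 shared of 29). In z_NrKO it called 67 higher and 40 lower (12 shared of 18). For NrKO oocytes against Nrpp it called 64 higher and 38 lower and limma 57 and 50, with 39 shared (r = 0.874). All shared calls at every stage had the same direction.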

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

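The tests in this part were chosen after their results had been seen, except those of an earlier stage and of scaling at 8C, of effects between stages and of effects beyond the sum.

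The first pattern is 8C mz_NrKO replicate 1, whose rank correlation with its group (0.709) lies far below that of other libraries of the stage. A poor library stays open. Its median rank correlation of 0.798 with the mz_DHet libraries lies just above the lowest of a mz_DHet library (0.783, of the same date), and its TPM sum of 990786 is the lowest of its group, while its 11970 genes above 1 TPM lie within the range of the other 9 (11268 to 13778). A signature of 3209 genes was called between the 6 mz_NrKO and 15 mz_DHet libraries of 8 March 2022. On it replicate 1 scored -0.31, where the 21 mz_DHet libraries lay between -0.14 and 0.32 and the other 9 mz_NrKO between 0.47 and 1.13. Of those 9, only the 3 of 15 July 2022 (0.47 to 0.91) had no part in choosing the signature. A wrong genotype label may explain it but stays open. The mark chosen for it was a score inside the mz_DHet range, and the score of replicate 1 lies below that range. This does not argue against a wrong label, since the score lies even further from the other mz_NrKO. The collection date, 23 February 2022, stays open too. The mz_DKO library of that date scored 0.51, above the mz_DHet range, but it is a single library and the lowest mz_DKO. The mz_EKO library of that date (-0.28) was the lowest of its group. The 2 mz_DHet libraries of that date scored -0.144 and 0.144, since scores are set against the mz_DHet mean of each date. Of these, mz_DHet replicate 2 had the lowest Crip2 of the 21 (131.1 TPM) and the highest Rln3 and Cyp26a1 (12.26 and 23.99 TPM). Its Cdx2 (7.379 TPM) was low, but mz_DHet replicates 18 and 19 lay lower (0.6197 and 4.467). Its Obox8 (39.03 TPM) was exceeded in mz_DHet replicates 11 and 13 (56.79 and 79.69). This library also sets the centre for the score of mz_NrKO replicate 1, and what it says about the labels was not tested. Esrrb stood at 8.47 TPM in mz_NrKO replicate 1, below the other mz_NrKO (12.0 or more), and on that date at 2.235 TPM in mz_EKO, 4.979 in mz_DKO and 13.37 and 56.54 in mz_DHet. UMI reads could not decide, because no UMI library matched it, and a biological difference between embryos was not tested.

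The second pattern is the crowding of changed oocyte genes around Nr5a2, 5 of 18 within 10 Mb. Chance position was argued against by Fisher's exact test, one-sided (p = 1.07e-07). DNA linked to the deleted allele, such as a strain difference carried along in breeding, is a candidate explanation: 4 of the 5 genes (80%) went the same way in NrHet against Nrpp oocytes, against 5 of 14 changed genes elsewhere. This decides nothing, since the same NrHet libraries stand on opposite sides of the 2 comparisons and the share without a change is unknown. A direct effect of the loss on neighbouring genes is another, since 5 of 5 went the same way in m_NrKO and in mz_NrKO at E2C. In other groups fewer did, 3 of 5 in mz_NrKO and 2 of 5 in mz_DKO at L2C, 1 of 4 in each at 4C, 1 of 4 and 2 of 4 at 8C, and 2 of 5 and 0 of 5 in z_NrKO at E2C and L2C. These few genes bear on both explanations, which cannot be told apart by expression alone.

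The third pattern is the large number of changed genes in mz_NrKO at E2C and 8C. Library composition was argued against at 8C, where 96.1% of the genes were called again with median-of-ratios scaling. It stays open at E2C, where that scaling changed the balance of lower and higher genes. A delay at 8C may explain part of it. Of genes changed at least 2-fold, 72.6% shifted toward the 4C level in the median of 100 splits of the controls (65.1 to 78.2%, and 73.9% in mz_DKO). The share among all tested genes was not computed at 8C, so 50% cannot be taken as the chance value. For a delay 90% or more was set in advance, and against one a share under 75% in every split. The 72.6% lies between these bounds, so a delay stays open. At E2C 87.8% of the 674 genes (592, of which 534 lower and 58 higher) shifted toward the oocyte level, against 62.4% of all genes tested, and a delay could not be told apart there from failed activation, since both lower the same genes. The share was not computed for calls with median-of-ratios scaling or without mz_NrKO replicate 1, where lower and higher genes were more even.

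Further results stood out by their values. In 56 checks of the highest and lowest library in 14 groups, where chance marks about 1 in 20, 4 libraries lay far from their group. Oocyte Nrpp replicate 4 had 12589 genes above 1 TPM (others 11392 to 11926). L2C mz_NrKO replicate 7 had Esrrb at 56.9 TPM (others 4.09 to 27.8). The TPM sum of 8C mz_NrKO replicate 1 was 990786 (others 994327 to 995883) and that of 8C mz_DKO replicate 1 was 991996 (others 993818 to 995005). Effects of Nr5a2 loss differed between stages in 317 genes for 8C against L2C and 265 for 8C against 4C, and those of the double loss from the sum of the single losses in 4 genes, each by a test of the difference itself.

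Genes held only in the UMI table, which enter the report only within counts from UMI reads, also changed at 8C. Of 49 tested, 17 changed in 5 mz_NrKO against 16 mz_DHet libraries (10 higher, 7 lower), 24 in 9 mz_DKO (15 higher, 9 lower) and 15 between mz_NrKO and mz_EKO (10 higher, 5 lower). Ctsl, the lysosomal protease cathepsin L, rose from 577 ± 267 to 2100 ± 518 TPM in mz_NrKO (log2 fold change 1.94 ± 0.26), and Pttg1, which is securin, fell (-1.47). Without the UMI library labelled mz_DHet replicate 12 the counts were 22, 28 and 19.

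Chance as the source of each count was set against 100 splits of the same libraries, the real one included. At E2C the real 674 genes of mz_NrKO were reached by 1 split (highest other 1), the 32 of m_NrKO by 1 (20) and the 35 of the controls by 1 (1). In oocytes the 19 of NrKO were reached by 1 split (1) and the 3 of NrHet by 3 (30). The 18, 20 and 14 genes of mz_NrKO, mz_DKO and z_NrKO at L2C were each reached by 1 split (3, 6 and 7), as were the 88 of mz_NrKO and 336 of mz_DKO at 4C (1 and 1). At 8C 1 split reached the 3075 of mz_NrKO (37), the 3669 of mz_DKO (1), the 2466 between mz_NrKO and mz_EKO (394) and the 4 beyond the sum (3), while 2 splits reached the 1 of mz_EKO (1) and 4 the 16 between mz_DKO and mz_NrKO (53). Between stages 1 split reached the 317 (221) and 1 the 265 (44), and in control development 1 split each reached the 2572 (451), 6044 (3), 6122 (1), 3071 (1222) and 224 (68). Taken singly, each of these was reached by fewer than 5 of 100 splits, the bound set for chance, but this does not exclude chance. The splits mixed libraries across dates, so they lack the uneven dates of the real groups and any shared mothers. In control development they mixed the stages, so a lower count was largely fixed in advance. With 100 splits the smallest share is 1 in 100, so none could pass a Bonferroni allowance for the number of counts. The weakest are the 3 of NrHet oocytes, the 1 of mz_EKO and the 16 between mz_DKO and mz_NrKO, which other splits reached, and the 4 beyond the sum, where another split gave 3. For counts of 0 the splits decide nothing, since all 100 reach 0 by design, in z_NrKO (highest other 6) and between mz_NrKO and m_NrKO (2) at E2C, and in mz_EKO at L2C (32) and 4C (3). Some splits called several times the real count, 30 against 3, 53 against 16 and 32 against 0, and the cause was not tested.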

How the results depend on the processing

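The alternatives with pseudocounts of 0.1 and 5 TPM, those without libraries standing apart, control development without a filter and those for correlations of effects were chosen after the data had been seen, and the others were planned. Of 263 alternative values of 29 counts, 168 stayed within a factor of 1.5 of the value reported, where a count of 0 had to stay 0. Of 2547 for 238 values of named genes in single comparisons 2107 kept direction and call, 427 lost the call, 3 gained it and 10 reversed. Depth is unknown, and simulated 2-fold changes were recovered in 25.4% of cases at L2C and 23.9% at 4C, which limits what absence of a call says there. The 4C mz_EKO count on a single date was not run, since a group had fewer than 2 libraries, nor was a DESeq2 Wald test, which needs counts. Except where fewer genes or libraries entered the fit, the cause was not tested.

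Without the filter 3 genes passed in NrKO oocytes, and at E2C 411 in mz_NrKO, 16 in m_NrKO and 2 in z_NrKO. At L2C that setting gave 28 in mz_NrKO and 16 in mz_EKO. At 4C it gave 26 in mz_NrKO and 188 in mz_DKO, at 8C 2 in mz_EKO, and between stages 552 (8C against L2C) and 414 (8C against 4C). Without the date factor 4 passed in NrKO and 0 in NrHet oocytes, and 176 in m_NrKO, 1 in z_NrKO, 13 between controls and 1 between mz_NrKO and m_NrKO at E2C. At L2C it gave 1527 in mz_NrKO, 296 in mz_EKO, 84 in mz_DKO and 8 in z_NrKO. At the later stages it gave 1 in mz_EKO and 214 in mz_DKO at 4C; 0 in mz_EKO, 0 beyond the sum and 7 between mz_DKO and mz_NrKO at 8C, and 1815 for 8C against L2C. With Nrpp as the control 57 genes were higher and 50 lower in NrKO oocytes (1.1e+02 in all), and 233 passed in mz_NrKO and 18 in z_NrKO at E2C. Median-of-ratios scaling gave 392 in m_NrKO and, between controls at E2C, 52 higher and 52 lower (1.0e+02 in all). With a block for the library number, which pairs nothing, 8 passed in NrHet oocytes, 12 in m_NrKO and 7 between controls at E2C, and 4 in mz_NrKO and 13 in mz_DKO at L2C. It gave 8 in mz_NrKO and 118 in mz_DKO at 4C, 1717 in mz_NrKO, 1 beyond the sum (not of the 4) and 2 between mz_DKO and mz_NrKO at 8C, and 58 for 8C against L2C. For 8C against 4C it gave 39 higher and 65 lower. It moved the correlation of mz_NrKO and mz_EKO effects to 0.255.

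UMI reads called 0, 2 and 2 genes in mz_NrKO, mz_DKO and z_NrKO at L2C, 17 and 125 in mz_NrKO and mz_DKO at 4C, and 0 beyond the sum and 3 between mz_DKO and mz_NrKO at 8C. A single date, with a filter of its own (17598 genes tested at L2C), gave 6, 8 and 4 in mz_NrKO, mz_EKO and mz_DKO at L2C, 33 in mz_NrKO at 4C, 2 beyond the sum (neither of the 4) and 4 between mz_DKO and mz_NrKO at 8C. A pseudocount of 0.1 gave 9 in z_NrKO at L2C, and one of 5 gave 22 there, 1 in z_NrKO and 1 between mz_NrKO and m_NrKO at E2C, and 40 between mz_DKO and mz_NrKO at 8C. Without the libraries standing apart 409 passed in m_NrKO, 1 in z_NrKO, 2 between mz_NrKO and m_NrKO and, between controls, 45 higher and 56 lower at E2C, 8 between mz_DKO and mz_NrKO at 8C, and 582 and 583 between stages. Control development gave 5484, 9171, 9308, 6212 and 839 genes at 2-fold or more (E2C, both L2C, 8C and 4C), and 1240, 3985, 4047, 1704 and 77 with a pseudocount of 5. Of the 52 calls on gene lists 2 held with an estimated correlation. The correlation of mz_NrKO and mz_DKO effects was 0.822 without the filter, 0.813 without the date factor and 0.849 with a pseudocount of 0.1, and that of mz_NrKO and mz_EKO 0.12 on a single date.

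Leaving out each mz_DHet library at L2C in turn gave 4 to 16 genes in mz_NrKO (4 without replicate 6, 8 without 7) and 11 to 20 in mz_DKO (11 and 13 without 3 and 7), where 24 passed without mz_NrKO 6. Leaving out each library at 4C in turn gave 27 to 91 in mz_NrKO (27 and 31 without mz_NrKO 2 and 1; 54, 42 and 32 without mz_DHet 4, 5 and 6). It gave 0 to 3 in mz_EKO (3 without mz_EKO 1) and 208 to 325 in mz_DKO (215, 218, 208 and 223 without mz_DHet 3, 4, 5 and 6). Reversed values belonged to no called gene except Hmga1b. They were Nr5a2 in z_NrKO at E2C (-0.008 with scaling, -0.06 with the replicate block, -0.27 against mz_Nrpp), Nr5a2 in mz_NrKO at L2C (-0.35 without the date factor, -0.032 on a single date, -0.11 without mz_DHet 7), Esrrb in mz_DKO at L2C (0.14 without mz_DHet 7), Esrrb in mz_EKO at 4C (0.38 and 0.06 without mz_EKO 1 and 4) and Hmga1b in mz_NrKO at E2C (-0.33 against mz_Nrpp). Among fits that left out a library, the other ends of these ranges were 0.234 for Nr5a2 at L2C (without mz_NrKO 6), -0.423 for Esrrb at L2C (without mz_DHet 6) and -0.601 for Esrrb at 4C (without mz_EKO 3).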

Other observations

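The genes and groups in this part were picked after their values had been seen, and no explanation of them was tested. The genes below are examples called in more than 1 comparison of embryos without Nr5a2, across stages or kinds of loss. All such genes were not counted, and many more were shared by mz_NrKO and mz_DKO at 8C. Tlk2 fell in mz_NrKO at L2C (log2 fold change -2.59 ± 0.47) and 4C (-2.90 ± 0.39), and in z_NrKO at L2C (-1.82 ± 0.40). Ppp1r16b fell in z_NrKO at L2C (-2.95 ± 0.54) and in mz_NrKO at 4C (-3.56 ± 0.54), and its effect at 8C differed from that at 4C (4.46 ± 0.63). Oaz3 rose in z_NrKO at L2C (3.38 ± 0.64) and in mz_NrKO at 8C (1.71 ± 0.40, adjusted p = 0.000916, higher in 7 of 10). Ccdc137 fell at L2C in mz_NrKO (-1.52 ± 0.28) and z_NrKO (-1.27 ± 0.24), and Rln3 rose at 4C and 8C in mz_NrKO (2.98 ± 0.64 and 4.05 ± 0.50).

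Groups outside the trophectoderm and the 2-cell burst had called genes in mz_DKO at 8C without a call as sets by camera in full-length values. Mitosis had 21 of 66 genes up and 6 down (23 and 6 adjusted over the list alone), with the kinesin Kif2c rising (1.64 ± 0.30, adjusted p = 1.43e-05, higher in 10 of 10) and Cdk1 falling (-1.32 ± 0.18). Stress genes had 9 of 21 up and 3 down (10 and 3 adjusted over the list alone), and fry called that list (adjusted p = 0.0134) but not mitosis (0.18). In UMI reads camera called mitosis as higher (adjusted p = 0.0295). Oxidative phosphorylation had 6 of 71 up and 11 down (5 and 9 adjusted over the list alone), Cox5a (-0.73 ± 0.16) among the falls. Cholesterol synthesis had 6 of 25 up and 6 down, Fdft1 (-1.51 ± 0.21) among the falls (7 and 6 adjusted over the list alone). The p53 target Perp rose from 142 ± 63.1 to 377 ± 102.4 TPM (1.28 ± 0.23, adjusted p = 1.38e-05).

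Other values belong to single libraries. L2C mz_NrKO replicate 6 had a rank correlation of 0.738 with its group, a TPM sum of 887003 and Nr5a2 at 113.8 TPM, against 500 ± 172 in the other 9. The UMI library labelled mz_DHet replicate 12 at 8C had Cdx2 at 0 TPM, Crip2 at 18 TPM and Rln3 at 146 TPM, where the other UMI mz_DHet libraries had Cdx2 between 24.9 and 214 TPM, and it correlated best with full-length mz_NrKO replicate 7 (r = 0.666). With it left out, UMI reads called 2722 genes in mz_NrKO at 8C and 3603 in mz_DKO, against 2272 and 3099 with it.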
